A study of Arabidopsis thaliana with 4 samples.

How the data were processed

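The series holds 4 two-colour Agilent arrays, each hybridised with RNA of ang3 and of Ler. Per the labels, seeds were kept cold for 3 days, seedlings grew at 21 °C with 16 h of light, and 1 µg of RNA per sample was labelled together with spike-in transcripts. The arrays were imaged in 1 scan of 1 slide, so no batch could be tested and the slide could not be used as a block. The series text describes biological replicates in dye swaps, but it does not name which arrays form a swap or whether a swap shares its extracts. Each array was therefore counted as 1 replicate (n = 4). If arrays shared extracts, p-values would measure partly technical spread. As a check, the difference between replicates 1 and 3 was set against that between 2 and 4, with r = -0.26 over 20145 genes and 0.072 over the 5174 with an adjusted p of 0.5 or more. This does not settle the question.

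Per the file headers, spots were quantified with Agilent Feature Extraction 10.1.1.1, the version also named in the series text. The spot and local background intensity values used here are median pixel intensities per channel as deposited, with no normalization. The processed signal intensities are, per the file headers, background-subtracted with spatial detrending and dye-normalized within each array by linear and lowess factors. The deposited log10 ratio is that of processed red over processed green. It equalled the log10 of the processed signals within 0.001 for at least 67.9% of spots per array, and was listed at 0 for 23.3% to 32.1%. The deposited p-value of each log ratio comes from the authors' run of the Feature Extraction error model on 1 array at a time. Flags per the file headers mark spots well above background, saturated or non-uniform. The authors' series table holds log2 ratios of the processed signals for 32149 probes, already turned to ang3 over Ler on all 4 arrays (r of 1 or -1 and slope of 1 against the scanner values). Its column medians were -0.045, 0.026, 0.0077 and -0.097. It was found not to be centred, and the other 5329 probes were not above background on any array. The authors' criterion, per the series text, was a p under 0.05 with an absolute log2 ratio above 1.

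Analysis was run in R 4.3.3 with limma 3.58.1 and Python 3.11.15, and figures were drawn with matplotlib 3.10.9. Median spot signals and background medians were corrected with normexp (offset 50), and ratios were normalized within each array by loess. The design fixed before the data were examined had named mean spot signals. Medians were used because the files as analysed here give median signals only. Control spots were left out after the background step with weight 0 in loess, as were spots marked as outliers (12, 6, 12 and 4 on replicates 1 to 4). No spot was saturated.

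A probe was tested if well above background on at least 3 of 4 arrays in the channel of at least 1 genotype, which 20538 probes passed. Of 37478 probes 26236 name a locus (25665 loci, of which 25449 are in the reference), 8812 name a chromosome interval and 2430 a transcript without a locus. Names came from the array files through locus identifiers and the TAIR10.1 gene table, which was used for symbols and gene order only. The files name no genome build, so no coordinates are given. Spots of a probe were averaged and a locus was represented by its brightest probe, which left 18450 loci and 1705 unnamed probes. Of 366 loci with more than 1 tested probe, 1 had probes called in opposite directions. Near-identical genes can share hybridisation signal. A gene not above background in one genotype on any array was given a lower bound of its fold, from channel levels after loess and Aquantile against the lowest signal among probes well above background.

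Ratios were fitted with lmFit and eBayes with a dye intercept, genotype coded by dye orientation (residual degrees of freedom 2, prior 3.03), and p-values were adjusted by Benjamini-Hochberg. SE is that of the fit and SD the spread of the 4 ratios. The dye intercept takes up any difference between the arrays of the 2 dye orientations. SE and p-values therefore rest on the spread within an orientation and on the prior, and SE can be far below SD. The dye intercept itself passed for 0 genes with limma, and 3020 had an unadjusted p under 0.05. Gene lists (27 fixed before the data were examined, 26 with at least 5 tested members) were tested with camera at a preset correlation of 0.01, two-sided, and adjusted over the lists. An estimated correlation was used as an alternative. That test has only the 2 residual degrees of freedom, so small adjusted p-values are hard to reach with it. A list of cytosolic ribosomal proteins by locus was added after the annotation had been read. The fixed lists were adjusted among themselves and the added list over all 27. Named genes were RPL5B, RPL5A, the 12 highest and 12 lowest among genes past the threshold with the same sign on 4 arrays, and up to 3 members with the smallest p of each list, or the 1 with the smallest p where none passed.

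The procedure was tested on simulated data for ang3 against Ler with 4 arrays and 20155 genes. It recovered 100% of 100 genes changed by a log2 ratio of 1 and 97% of 100 changed by 0.5, with 14 false calls among 211. A simulated list of 20 genes shifted by 0.3 was detected, and 0 of 27 other lists were called. The simulated noise was independent between genes, so the list result does not measure false calls among genes that vary together.

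Alternatives were the processed signals, normexp with offset 0, no background correction, median centring, Aquantile, the series table, no filter, a filter on all arrays and channels, no dye term, separate channels, other treatment of multiple probes, an intensity trend with a robust prior, unadjusted p, the deposited p per array, leaving out each array, an estimated correlation, and fry. The effects of most of them are given in the closing section.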

Results

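Transcript levels were compared between the Arabidopsis mutant ang3 and its control accession Landsberg erecta (Ler) on 4 two-colour oligonucleotide arrays. Each array held ang3 RNA in one dye and Ler RNA in the other. The mutant was labelled with Cy5 on replicates 1 and 3 and with Cy3 on replicates 2 and 4. The RNA came from the green parts of seedlings, which the series text lists as the shoot meristem, the young leaves and the cotyledons, grown at 21 °C with 16 h of light. The sample labels give growth stage 1.02 and name the tissue shoot apex, whereas the series text gives stage 1.03. Between 19224 and 21332 of 37478 probes per channel were well above background. All ratios below are ang3 over Ler on the log2 scale, with the direction taken from the dyes in the labels, as the mean of 4 arrays. The number of arrays limits the precision of every value.

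The log2 ratios of 20145 genes correlated across genes with r between 0.387 (replicates 1 and 2) and 0.733 (replicates 2 and 3). Genes are not independent replicates. The standard deviation of the ratios was 0.198 on replicate 1 and 0.285 to 0.335 on the other arrays. The submitters describe biological replicates in dye swaps, without stating which extracts were shared between arrays.

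The question of the design was which transcripts differ between ang3 and Ler. As background, ang3 is known as an allele of RPL5B (AT5G39740), a gene of a protein of the large cytosolic ribosomal subunit. The RPL5B ratio was -0.04 (SE 0.069, SD 0.22, n = 4; adjusted p = 0.70). It was -0.36 on replicate 1 and 0.02 to 0.10 on the others, and the probe therefore gave no check of the labels. The transcript of the paralog RPL5A (AT3G25520) rose by 0.26 (SE 0.045, SD 0.23, n = 4; adjusted p = 0.018), and was higher on 3 of 4 arrays. Its ratio was -0.01 and 0.15 on replicates 1 and 3, with ang3 in Cy5, against 0.51 and 0.39 on replicates 2 and 4. The call for RPL5A was lost without a dye term (adjusted p = 0.085), without replicate 2 (adjusted p = 0.070) and without replicate 3 (adjusted p = 0.0998). With median centring its ratio was 0.42 (adjusted p = 0.0026).

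The largest increase was at AT4G16215, whose transcript was 61.8-fold higher in ang3 (log2 ratio 5.95, SE 0.12, SD 0.44, n = 4; adjusted p = 0.00052). AT1G58025 followed (log2 ratio 4.32, SE 0.049, SD 1.1, n = 4; adjusted p = 6.4e-05), with 5.25 and 5.30 where ang3 carried Cy5 against 3.48 and 3.26 where it carried Cy3. AT3G54730 and AT5G53230 rose by 3.28 and 3.24. ACC2 (AT1G36180), a homomeric acetyl-CoA carboxylase gene, rose by 2.72 (SE 0.076, SD 0.31; adjusted p = 0.0010). AT1G17960, AT5G60250, AT4G05380 and AT2G34655 were 6.48-, 5.67-, 5.25- and 4.59-fold higher. PR2 (AT3G57260), a pathogenesis-related glucanase gene of salicylic acid responses, rose by 2.16 (SE 0.30, SD 1.02; adjusted p = 0.013), with 0.76 on replicate 1 and 2.26 to 3.22 on the others. AT1G13470 rose by 1.99 (SD 1.04), from 0.57 on replicate 1 to 3.08 on replicate 2. AT5G59390 was not well above background in Ler on any array and was at least 3.92-fold higher in ang3 (adjusted p = 0.0067).

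Decreases were smaller. ASPGB1 (AT3G16150), an asparaginase gene, had the lowest ratio at -1.43 (SE 0.11, SD 0.29, n = 4; adjusted p = 0.0074), a level 2.69-fold higher in Ler. NEET (AT5G51720), a gene of an iron-sulfur protein, fell by 1.34 (SE 0.24, SD 0.61; adjusted p = 0.019). AT1G11740 fell by 1.32 and CYP78A8 (AT1G01190), a cytochrome P450 gene, by a ratio of -1.09. AT5G18600 and AT5G02540 had ratios of -1.03 and -1.01. AT5G09300, PGL5 (AT5G24420) and AT2G36885 had ratios of -0.98, -0.97 and -0.96, and AT5G09300 had the closest arrays of the 12 lowest genes (SD 0.075). AT5G44440, above background on 2 of 4 arrays in ang3, had a ratio of -0.96. AT3G15450 and FER1 (AT5G01600), a ferritin gene, both stood at -0.93. Each of these 12 genes was lower in ang3 on 4 of 4 arrays, as the rule for choosing them required.

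**Figure D1:**
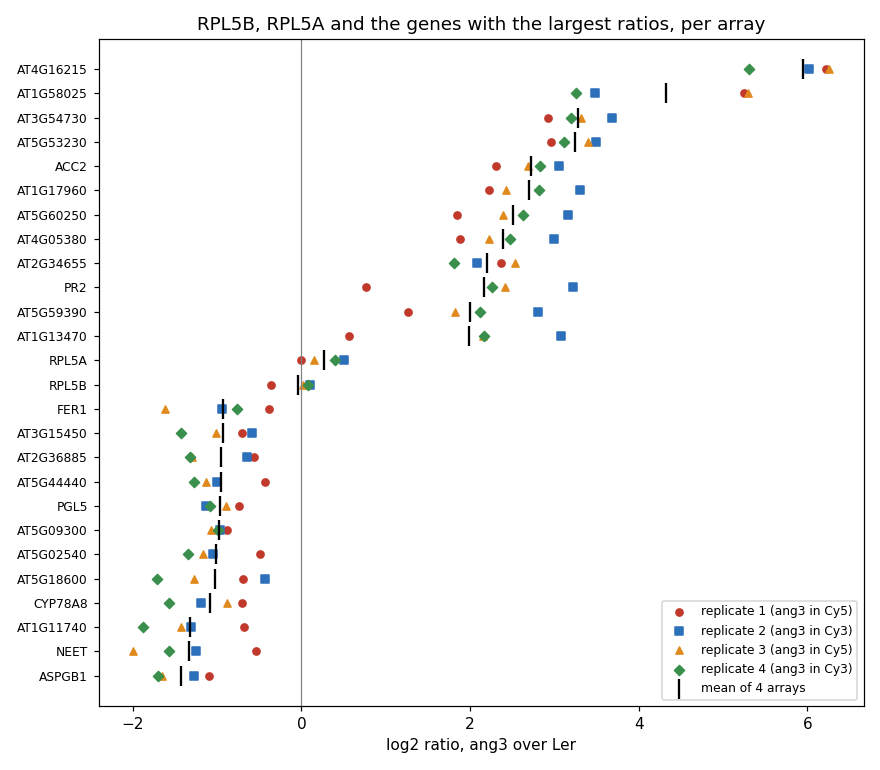
Log2 ratio of ang3 over Ler (horizontal axis) on each array for RPL5B, RPL5A and the 12 genes with the highest and 12 with the lowest ratios (vertical axis); symbols are single arrays and black bars the mean of 4. The ratios of AT4G16215 lie between 5.30 and 6.25, those of RPL5B between -0.36 and 0.10, and replicate 1 lies nearest 0 for PR2, AT1G13470 and NEET.

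Over all 20155 genes and unnamed probes tested, 3018 were higher and 2265 lower in ang3 at an adjusted p under 0.05 with limma, or 26.2% of those tested. Of these 5283, 4952 had the same sign on all 4 arrays, and the median size of their log2 ratios was 0.256. Over 2-fold, 101 were higher and 6 lower, against 315 and 69 with the processed signals and 172 and 12 with a normexp offset of 0. The 6 lower genes were ASPGB1, NEET, AT1G11740, CYP78A8, AT5G18600 and AT5G02540. The counts depended on each array: 1688 were higher and 1219 lower without replicate 1, 1162 and 915 without replicate 2, 374 and 162 without replicate 3, and 1607 and 922 without replicate 4. With each array centred on its median in place of loess, the median log2 ratio of all genes moved from 0.011 to 0.143, and 94.2% of the called genes were higher, against 57.1%. With the processed signals the excess turned, with 2124 higher and 2417 lower, or 46.8% higher.

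Most measured genes of the cytosolic ribosome and of ribosome biogenesis rose. Of 208 measured cytosolic ribosomal protein genes, a list by locus written after the array annotation was read and before any expression value was seen, 151 rose, 1 fell and 56 did not pass. Adjusted over the list alone, 175 rose and 1 fell. AT1G23410 rose by 1.16 (SE 0.043, SD 0.071, n = 4; adjusted p = 0.0016), AT5G39850, which lies within 100 genes of RPL5B, by 0.81 and RPSAb (AT3G04770) by 0.51, with 0.38 at a further RPSAb probe. The gene that fell was RPL3B (AT1G61580), with a ratio of -0.78 (SE 0.095, SD 0.24; adjusted p = 0.011), named here after its value was seen. The median of the list was 0.27 and the set was shifted upward (camera with a preset correlation, adjusted p = 7.5e-26; adjusted p = 0.58 with an estimated correlation). With median centring 199 rose and the median was 0.43, or 0.29 above that of all genes. With the processed signals 129 rose and 2 fell, with a median of 0.29. Of 27 ribosome biogenesis genes, 23 rose, none fell and 4 did not pass, and 24 rose adjusted over the list alone. NUC-L2, a nucleolin gene, rose by 1.68 (SE 0.052, SD 0.40; adjusted p = 0.0010), FIB2, a fibrillarin gene, by 0.84 and NSN1, a nucleostemin-like GTPase gene, by 0.58. The list median was 0.36 (camera, adjusted p = 1.1e-11; adjusted p = 0.61 with an estimated correlation). The list fixed by gene names starting with RPL, RPS or RPP held 53 tested genes, of which 23 rose, 4 fell and 26 did not pass (26 rose and 5 fell adjusted over the list alone; median 0.15; camera adjusted p = 0.0039; adjusted p = 0.84 with an estimated correlation). With median centring 36 of these rose and 1 fell, and 15 rose and 5 fell with the processed signals. STV1 rose by 0.33 in it, and 3 of the 4 that fell, RPL12-A (-0.32), RPL12-C (-0.39) and RPL27 (-0.21), encode proteins of the plastid ribosome. That list also took in disease resistance genes and lacked most of the ribosomal protein genes.

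Most measured genes of the photosynthesis and plastid ribosome lists had ratios below 0. Of 18 photosynthesis genes, 13 fell, 1 rose and 4 did not pass, and 16 fell and 1 rose adjusted over the list alone. LHCB1.3 and LHCB1.1, near-identical genes of a light-harvesting protein, had ratios of -0.44 and -0.39. LHCB1.3 was at -0.79 and -0.67 with ang3 in Cy5 against -0.24 and -0.07 in Cy3, and LHCB1.1 at -0.07 and -0.08 in Cy5 against -0.81 and -0.59 in Cy3. The gene that rose was RBCS2B, of the small subunit of Rubisco, at 0.41 (SE 0.034, SD 0.14, n = 4; adjusted p = 0.0074). The list median was -0.27 (camera, adjusted p = 3.5e-06; adjusted p = 0.61 with an estimated correlation). With the processed signals 9 of these genes fell, and 4 with median centring. Of 17 genes of the plastid ribosome, 10 fell, 1 rose and 6 did not pass, and 11 fell and 1 rose adjusted over the list alone. PSRP2, PRPL28 and RPS1 had ratios of -0.33, -0.29 and -0.23, and RPL3P rose by 0.27. Their list had a median of -0.18 (camera, adjusted p = 3.3e-05; adjusted p = 0.61 with an estimated correlation). With the processed signals 3 plastid ribosome genes fell. With median centring 0 fell, 1 rose and the list mean was 0.01 instead of -0.15, although the list was still called below the other genes (camera, adjusted p = 0.0039).

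Most measured genes of the flavonoid and salicylic acid lists rose, by amounts that differed between arrays, whereas most of the jasmonate and glucosinolate lists did not pass. Of 13 flavonoid and anthocyanin genes 12 rose and 1 did not pass, and 13 rose adjusted over the list alone. F3'H, which hydroxylates flavonoids, rose by 1.16, the regulator TT8 by 0.94 and the chalcone isomerase gene CHI (AT3G55120) by 0.39. The flavonoid median was 0.94 (camera, adjusted p = 4.7e-07; adjusted p = 0.61 with an estimated correlation), and its mean was 0.56 on replicate 1 and 1.37 on replicate 4. With the processed signals the flavonoid median was 1.44, and 10 flavonoid genes rose. Of 10 salicylic acid defence genes 8 rose and 2 did not pass, and 9 rose adjusted over the list alone. NIMIN1 rose by 0.99 (SD 0.89), WRKY70 by 0.82 (SD 0.61) and PAD4 by 0.58 (SD 0.39), all 3 of them regulators in salicylic acid signalling. Ratios of these 3 genes differed between the dye orientations, which cannot be told apart from a difference of replicates 1 and 3 from replicates 2 and 4. NIMIN1 was at -0.005 and 0.48 with ang3 in Cy5 against 1.70 and 1.77 in Cy3. WRKY70 was at 0.19 and 0.44 in Cy5 against 1.47 and 1.18 in Cy3, and PAD4 at 0.12 and 0.39 against 0.86 and 0.94. The salicylic acid median was 0.85 (camera, adjusted p = 8.1e-05; adjusted p = 0.61 with an estimated correlation). The mean of that list was 0.17 on replicate 1 and 0.78 on replicate 3, against 1.42 and 1.09 on replicates 2 and 4. Of 11 jasmonate and wounding genes 5 rose and 6 did not pass, with 5 also adjusted over the list alone. VSP2 and VSP1, of vegetative storage proteins, rose by 0.92 and 0.53, and LOX2, OPR3 and AOS, of jasmonate synthesis, by 1.00, 0.42 and 0.41. The jasmonate median was 0.42 (camera, adjusted p = 0.015; adjusted p = 0.61 with an estimated correlation), and the list's mean was 0.12 on replicate 1 and 0.42 to 0.65 on the others. Of 16 glucosinolate genes 7 rose and 9 did not pass, with 7 also adjusted over the list alone. They included CYP83A1 (0.28), MYB28 (0.22) and SOT18 (0.19), and the median was 0.14 (camera, adjusted p = 0.013; adjusted p = 0.61 with an estimated correlation). The mean of the glucosinolate list was 0.27 on replicate 3 and 0.07 to 0.14 on the others. With the processed signals 3 glucosinolate genes rose, and with median centring 11 glucosinolate and 7 jasmonate genes rose.

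**Figure D2:**
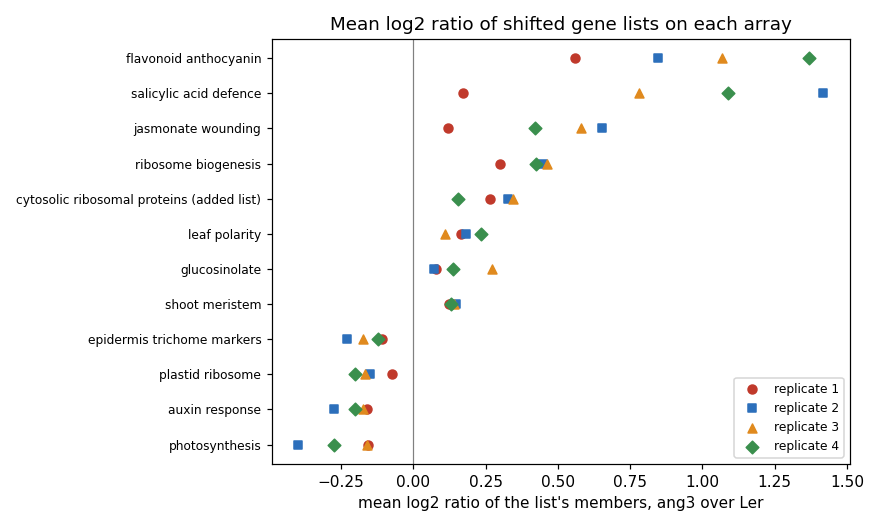
Mean log2 ratio of ang3 over Ler (horizontal axis) of the members of 11 shifted fixed lists and of the cytosolic ribosomal protein list by locus (vertical axis), with a symbol per array; the fixed list by RPL, RPS and RPP names is left out. The salicylic acid defence list spans 0.17 on replicate 1 to 1.42 on replicate 2, whereas the shoot meristem list lies between 0.12 and 0.15.

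Of 20 auxin response genes, 9 fell and 11 did not pass, and 12 fell adjusted over the list alone. The early auxin response genes IAA6, IAA19 and IAA2 had ratios of -0.53, -0.41 and -0.25. The auxin median was -0.20 (camera, adjusted p = 1.1e-05; adjusted p = 0.61 with an estimated correlation). With median centring 2 auxin genes fell and 1 rose, and 7 fell with the processed signals. Of 9 epidermis and trichome genes, 4 fell and 5 did not pass, with 4 also adjusted over the list alone. GL2 and TRY, regulators of trichome patterning, had ratios of -0.49 and -0.35, FDH, of cuticle formation, -0.19 and GL1 -0.20. Over the list the median was -0.13 (camera, adjusted p = 0.013; adjusted p = 0.66 with an estimated correlation), and 2 of its genes fell with median centring. Of 13 leaf polarity genes, 6 rose and 7 did not pass, and 8 rose adjusted over the list alone. YAB5 rose by 0.45, KAN2 by 0.29 and ARF4 by 0.28, all of them associated with the abaxial leaf side. The list median was 0.15 (camera, adjusted p = 0.0028; adjusted p = 0.61 with an estimated correlation), and 3 genes rose with the processed signals and 10 with median centring. Of 10 shoot meristem genes, 4 rose and 6 did not pass, and 6 rose and 1 fell adjusted over the list alone. The homeobox genes STM, KNAT1 and KNAT6 rose by 0.36, 0.32 and 0.19, and PNY by 0.14. The list median was 0.13 (camera, adjusted p = 0.024; adjusted p = 0.61 with an estimated correlation), and this call was lost with median centring (adjusted p = 0.19). With the processed signals 6 meristem genes rose and the median was 0.20 (camera, adjusted p = 0.0055).

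The remaining 14 tested lists were not shifted. Of 9 stomatal lineage genes SDD1 (-0.60), MUTE (-0.40) and SPCH (-0.22) fell, none rose and 6 did not pass, and 5 fell and 1 rose adjusted over the list alone (camera, adjusted p = 0.11; adjusted p = 0.89 with an estimated correlation), whereas the list was called lower without replicate 1 (adjusted p = 0.019). Of 22 mitosis genes CYCB1;3 (0.41), CYCB1;1 (0.39) and CDC20.2 (0.22) rose, PLE (-0.16) and HIK (-0.15) fell and 17 did not pass, and 3 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.81). Of 16 DNA replication genes TSO2 (0.51) and RNR1 (0.24), both of ribonucleotide reductase, rose and 14 did not pass, with 2 also adjusted over the list alone (camera, adjusted p = 0.72). Of 14 CDK inhibitors and endoreduplication genes SMR7 (0.81), KRP6 (0.50) and KRP7 (0.16) rose and 11 did not pass, with 2 adjusted over the list alone (camera, adjusted p = 0.43). A further KRP6 probe gave 0.08 (adjusted p = 0.14). Of 22 leaf growth regulators GRF6 (0.45), AN3 (0.31), GRF3 (0.29) and ANT (0.19) rose and 18 did not pass, with 1 adjusted over the list alone (camera, adjusted p = 0.81). Of 18 histone genes GAMMA-H2AX rose (0.21), HTA9 (-0.27) and HTA13 (-0.22) fell and 15 did not pass, with 1 and 2 adjusted over the list alone (camera, adjusted p = 0.76). Of 12 cold and dehydration genes COR15B (0.62), ERD10 (0.35) and KIN2 (0.27) rose, RAB18 fell (-0.42) and 8 did not pass, and 4 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.27).

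Of 23 expansin genes PNP-A (0.75) and EXPA20 (0.55) rose, EXPA16 (-0.54), EXLA1 (-0.34), EXPA8 (-0.28) and EXLA3 (-0.22) fell and 17 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.81). Of 20 xyloglucan endotransglucosylase genes TCH4 (0.34) and XTH18 (0.22) rose, XTH6 (-0.53), XTH15 (-0.34) and XTH10 (-0.13) fell and 15 did not pass, with 3 and 3 adjusted over the list alone (camera, adjusted p = 0.81). Of 6 heat shock genes HSP90.1 (0.51) and HSP23.6 (0.33) rose, HSP70 (-0.71) and HSFA2 (-0.42) fell and 2 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.89). Of 9 evening genes of the circadian clock ELF4 fell (-0.42, adjusted p = 0.049) and 8 did not pass, and none passed adjusted over the list alone (camera, adjusted p = 0.98). Of 5 morning genes RVE8 rose (0.34) and 4 did not pass, and 2 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.82). Of 10 vascular genes the sucrose transporter gene SUC2 fell (-0.42) and 9 did not pass, with 1 also adjusted over the list alone (camera, adjusted p = 0.91). None of 8 root genes passed over all genes or adjusted over the list alone, with CASP1 at -0.10 (adjusted p = 0.10; camera for the list, adjusted p = 0.72). The seed storage list had EM6 as its only tested gene, at -0.20 (adjusted p = 0.65), and was not tested. Up to 3 genes per list were named by the rule fixed in advance, and RPL3P, RPL12-C, RPL27, GL1, PNY, LOX2, AOS, PLE, HIK, ANT, KIN2, PNP-A, EXLA1, EXLA3, XTH18, XTH10 and HSP23.6 after their values were seen. Median and mean differed in sign for the histone, heat shock, vascular, DNA replication, expansin and root lists, and the test direction was downward where the median was positive for histones and heat shock, and where the mean was positive for DNA replication, expansins and roots. For the vascular list the test direction was upward and the mean negative. With median centring more members passed as higher in each of these 14 lists other than heat shock (2 and 2) and root genes (0 and 0). There 7 mitosis genes rose and 0 fell, 6 and 0 histone genes, 7 and 1 expansins, 7 and 2 xyloglucan endotransglucosylases, 5 and 1 vascular genes, 7 and 0 cold and dehydration genes, 3 and 0 evening genes and 1 and 2 stomatal lineage genes. Likewise 8 leaf growth regulators, 6 CDK inhibitors and endoreduplication genes, 3 DNA replication genes and 3 morning genes rose and none fell. None of these lists was shifted with that scaling either (camera, adjusted p from 0.060 to 0.96), and their medians lay from -0.18 (stomatal lineage) to 0.31 (morning genes) relative to that of all genes.

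**Figure D3:**
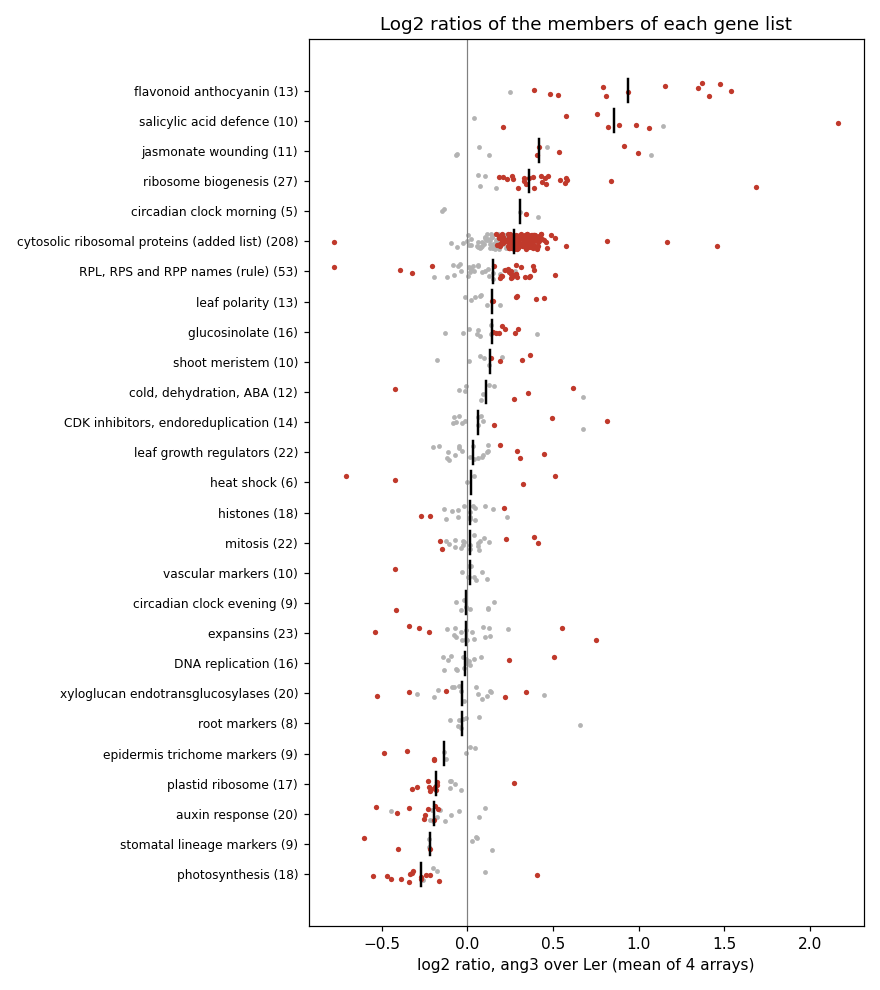
Log2 ratio of ang3 over Ler (horizontal axis, mean of 4 arrays) of each tested member of each gene list (vertical axis, number of tested members in parentheses); red points passed an adjusted p under 0.05 over all genes, grey points did not, and black bars are list medians. Medians lie between 0.94 for the flavonoid list and -0.27 for the photosynthesis list, and 151 of the 208 cytosolic ribosomal protein genes are red points above 0.

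In total 12 of 26 tested fixed lists were shifted, 8 upward and 4 downward, with the preset correlation of 0.01. None of these calls held with an estimated correlation, where adjusted p ranged from 0.61 to 0.99 and 0 lists had an unadjusted p under 0.05. That test had 2 residual degrees of freedom, with which a small adjusted p is hard to reach, so it neither upholds nor refutes the calls. The preset correlation in turn also called lists under other sign patterns of the arrays, as given below. With fry, which tests whether a list moves one way without comparing it with other genes, 0 lists passed after adjustment (lowest adjusted p = 0.058) and 13 had an unadjusted p under 0.05. With median centring the medians of the auxin, plastid ribosome and epidermis lists were -0.02, -0.03 and 0.01, which remained below the median of all genes at 0.143.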

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

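The tests of linkage, of dividing cells, of 1 factor on all plant genes and of other sign patterns for the count of genes were chosen after the result was seen. Of 129 values with 4 arrays each, 3 had 1 array set apart from the others by a gap test, and chance sets apart about 1 in 20. KRP7 stood at 0.26 on replicate 1 against 0.12 to 0.13 on the others. SUC2 was at -0.71 on replicate 4 and between -0.34 and -0.32 on the others. The vascular list had a mean of -0.078 on replicate 4 and of 0.0049 to 0.018 on the others, and SUC2 is a member of that list.

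Ratios were smaller on replicate 1, where the slope over 5281 called genes on the mean of the other arrays was 0.558, against 1.04 to 1.2 on the others. Compression of all ratios on that array was tested with the 10 spike-in transcripts, whose slope on replicate 1 was 0.929 (95% interval 0.854 to 1.005). The interval lies above the slope of the genes and above the bound of 0.8 set in advance for compression, though it includes the bound of 0.9 set against it. Control RNA mixed into the mutant sample would lower all lists by a similar share, and replicate 1 kept between 0.970 of the others' mean for cytosolic ribosomal proteins, a mean lowered by replicate 4, and 0.156 for salicylic acid defence, but this difference of 0.814 decides nothing because the shares differed by 1.16 to 2.30 on the other arrays, as between 1.66 for flavonoid genes and 0.496 for ribosomal proteins on replicate 4. Control RNA therefore stays open, a difference between the plants harvested for each replicate may also be involved, and no biological explanation was tested.

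The 12 highest genes, chosen for having 1 sign on all arrays, lay at scattered loci. Alleles linked to RPL5B, such as a segment carried along with the mutation, would place them near that gene, yet 0 of the 12 highest genes lay within 100 genes of RPL5B, and they fell on 5 chromosomes. Among the 92 placed loci over 2-fold higher, 0 lay in that window, in which 78 genes were tested. Further sequence differences between the mutant line and Ler elsewhere in the genome, and changes in expression, could each give such ratios. Neither was tested, since probe sequences were not used here.

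Of 208 cytosolic ribosomal protein genes 151 rose, 1 fell and 56 did not pass, whereas of 18 photosynthesis genes 13 fell, 1 rose and 4 did not pass, with 9 falling with the processed signals and 4 with median centring. An intensity-dependent trend of the log ratios would move other genes of like brightness, but the ribosomal list's median lay at percentile 100 and the photosynthesis median at percentile 0 of 10000 random lists matched on brightness, with loess and with median centring alike. A larger share of dividing cells in the mutant sample would raise division genes as well, and the upper quartile of 38 mitosis and DNA replication genes was 0.068 against a ribosomal median of 0.27. An effect of the genotype on ribosome production remains a hypothesis, and a difference in developmental stage or in the proportion of young leaf tissue may also be involved and was not tested. Both list calls rest on the preset correlation.

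With 4 arrays there are 8 sign patterns, too few for a share under 0.05. The real pattern called 5283 genes and the highest other pattern 0 with limma, where unadjusted p was under 0.05 for 53 to 3020 genes. Thus 1 of 8 patterns, the real one, gave as many. In the fit of the other patterns, except the one that follows the dyes, part or all of a genotype difference enters the residual spread. This makes calls harder to reach, and the 0 of those patterns is therefore no measure of false calls. The dye pattern was fitted with genotype as a covariate and also called 0, with 3020 genes at an unadjusted p under 0.05. It measures a difference between dye orientations. For the gene lists, 2 of 8 patterns shifted as many as the real 12, and the highest other also shifted 12, when the sign of replicate 1 alone was turned. The pattern that follows the dyes shifted 3, and the remaining ones shifted 6 to 11. Turning replicates 2 and 3, or 3 and 4, gives patterns that follow neither genotype nor dye, and each shifted 7. With the preset correlation, lists were therefore also called without a genotype contrast.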

How the results depend on the processing

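The ribosomal protein list by locus and the lists of other gene groups were added after the settings had been fixed, the former before and the latter after expression values were seen. Of the 5283 called genes 310 had the other sign with median centring and 1 with averaged probes, and 0 were called the other way in any refit of the ratios (limma). Higher and lower genes numbered 3018 and 2265, but 6952 and 425 with median centring and 4727 and 3622 with separate channels. They numbered 2319 and 1659 without a dye term, and 74.1% of the genes called with it were also called there. No background correction gave 3078 and 2609, an intensity trend with a robust prior 3370 and 2650, and no filter 2670 and 1973. The share higher was 57.1%, against 94.2% with median centring, 46.8% with the processed signals or the series table, and 69.8% without replicate 3. The counts ranged from 374 (without replicate 3) to 1688 (without replicate 1) higher and from 162 to 1219 lower, with 1162 and 915 without replicate 2 and 1607 and 922 without replicate 4. Of the genes called with 4 arrays, 10.1% were also called without replicate 3 and 50.9% without replicate 1. A 3-array fit has fewer arrays and unequal dyes. The fits without replicate 1 and without replicate 3 are alike in both, so neither explains the difference between them. Without replicate 3, replicate 1, with its smaller ratios, was the only array with ang3 in Cy5. Over 2-fold, 101 and 6 became 315 and 69 with processed signals, 315 and 70 with the series table, 172 and 12 with offset 0, 175 and 3 with median centring, and 114 and 6 with unadjusted p. A separate count took the deposited ratios, over 2-fold with a deposited p under 0.05 on each of 4 arrays, and gave 158 and 29. On single arrays it gave 265 to 672 higher and 138 to 183 lower. Leaving out arrays gave 68 (without replicate 3) to 164 (without replicate 1) higher and 3 to 17 lower, with 11 lower without replicate 2. RPL5A kept 0.26 without a dye term but lost its call (adjusted p = 0.085), and ranged from 0.22 (without replicate 3, adjusted p = 0.0998) to 0.30 without single arrays, with 0.42 (adjusted p = 0.0026) with median centring. RPL5B ranged from -0.13 to 0.06 without single arrays, was -0.16 with the processed signals and 0.09 with median centring, and was not called in any refit. Shifted lists numbered 12, but 0 with an estimated correlation (camera) and 0 with fry, where 0 and 13 lists had an unadjusted p under 0.05, and 12 to 13 without single arrays. The camera test with an estimated correlation had 2 residual degrees of freedom, so its count decides little. Relative to all genes, whose median moved by median centring to 0.143, each shifted list kept its direction, although the epidermis median itself and the plastid ribosome mean were both 0.01. With that scaling 11 lists were shifted, and the shoot meristem list lost its call (camera, adjusted p = 0.19). Of 96 named genes, 47 lost their call without replicate 3, 23 without replicate 2, 23 without replicate 4, 19 without replicate 1, 15 with processed signals and 12 with median centring. Without a dye term 9 lost it, and 7 with an intensity trend and robust prior. AT5G59390, AT5G44440, NIMIN1 and EM6 had no value under the filter on all arrays. Aquantile leaves the ratios as they are, and the slide as a block was not run because there was 1 slide. Except where the number of arrays explains it, the cause was not tested.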

Other observations

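The lists of DNA damage, sulfur deficiency and mitochondrial stress genes were written after the leading genes had been seen, and the genes seen by then were left out of the tests. Several genes of a DNA damage list were higher in ang3. GMI1 and NAC044, both known to respond to DNA damage, rose by 1.35 (SE 0.043, SD 0.13, n = 4) and 1.28 (SE 0.11, SD 0.44), and prompted the list. Of 13 other DNA damage genes, of which SMR5 is also in the list of CDK inhibitors, 8 rose and 5 did not pass, and 11 rose with adjustment within the list. BRCA1 rose by 0.51 (SD 0.055), RAD17 by 0.45 and PARP2 by 0.33, and SMR5 was at 0.68 without passing (adjusted p = 0.099). The list was shifted upward (median 0.31, camera, adjusted p = 1.85e-05; adjusted p = 0.12 with an estimated correlation), at percentile 99.99 of random lists matched on brightness. A DNA damage response in ang3 may underlie these increases, as a hypothesis, and the mutation and the history of the line were not separated.

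Several genes of a sulfur deficiency list were higher too. ATSDI1, known to be induced when sulfur is short, rose by 1.91 (SE 0.16, SD 0.66, n = 4) and LSU3 by 1.07. Of 11 other genes 7 rose and 4 did not pass, and 7 rose with adjustment within the list. SDI2 (AT1G04770) rose by 0.85 (SD 0.33), SULTR4;2, a sulfate transporter gene, by 0.79 (SD 0.42), LSU2 by 0.69 (SD 0.054) and APR1, of sulfate reduction, by 0.66 (SD 0.40). Replicate 1 was lower than the other arrays for most of these genes. It gave 0.37 for SDI2 against 0.89 or more, 0.22 for SULTR4;2 against 0.73 to 1.12 and 0.06 for APR1 against 0.80 to 0.92, but 0.62 for LSU2 against 0.69 to 0.74. SULTR1;2, which did not pass, was at -0.23 on it and at 0.18 to 1.32 on the others. The list median was 0.62 (camera, adjusted p = 0.000659; adjusted p = 0.25 with an estimated correlation). Among mitochondrial stress genes, AT2G21640 prompted the list with 1.00 (SE 0.054, SD 0.14, n = 4). Of 11 others 6 rose and 5 did not pass, and 8 rose with adjustment within the list. GSTU24 rose by 0.97 (SD 0.52), CYP81D8 by 0.81 (SD 0.50) and NDB2, an alternative NADH dehydrogenase gene, by 0.62 (SD 0.12), whereas AOX1A, the alternative oxidase gene often used as a marker of this response, was at -0.06 (adjusted p = 0.25). Replicate 1 gave 0.16 for CYP81D8 against 0.74 to 1.34 on the other arrays, 0.05 for OM66 (AT3G50930, named BCS1 in the annotation) against 0.42 to 1.04, and 0.46 for GSTU24 against 0.63 to 1.59. DTX1 and NAC013, which did not pass, were at 0.02 and -0.11 on replicate 1, against 0.52 to 1.37 and 0.18 to 0.35 on the others. The list median was 0.50 (camera, adjusted p = 0.000949; adjusted p = 0.22 with an estimated correlation). A sulfur deficiency response and a mitochondrial stress response in ang3 are hypotheses from the same data, and may not be specific, since several of these genes also respond to other stresses.

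Among the 92 placed loci over 2-fold higher, 5 pairs lay within 5 genes of each other, which 0.86% of 10000 random draws of tested loci reached. The draws took no account of neighbouring genes of 1 family, which can share hybridisation signal. This share therefore does not show that changed loci gather in the genome beyond such genes. The pairs were AT1G02920 with AT1G02930, AT2G43570 with AT2G43590, AT3G57240 with PR2, AT4G22870 with AT4G22880, and AT5G53230 with AT5G53240.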
